A study of Bacillus subtilis with 6 samples.

How the data were processed

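RNA was taken from colony biofilms of Bacillus subtilis grown for 24 h at 30 °C, with 3 biological replicates of wild type and 3 of a mutant lacking dnaK and tig, per the labels. Total RNA was isolated with a column kit and made into strand-specific libraries, per the labels' protocols. The aligner, the counting rule, the annotation and the genome build are not given in the sources used here. The authors deposited 1 table per sample with gene names, positions and TPM, per the file headers, and large values carry commas between groups of digits, which were removed. Each column then summed to 1000000. Gene positions are given as the files give them, counted from 1, and the files name no build or chromosome.

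The design was written before the data were examined and assumed counts. The tables hold TPM, so limma on log2 values took the place of a count test, as the design foresaw. TPM multiplied by gene length fell on whole multiples of a single step in each library: of 161 to 243 values of up to 20 reads per library, 100% lay within 0.1 of a whole number. The step gave the reads per library, used for depth, for the floor of 3 reads and for limma-voom as an alternative. The floor covers counting error only. Median reads per gene were 566.5 to 929.

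Of 4417 rows, 30 ribosomal RNA-like rows (10 named 5S rows and 20 unnamed rows of matching length beside them) and 87 unnamed rows of transfer RNA length were left out, and TPM were rescaled to 1000000. Libraries were scaled by an unweighted trimmed mean of log ratios, with 30% of log ratios and 5% of mean levels trimmed on each side. Genes with at least 1 TPM in at least 3 libraries were kept. Tests used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this scale, which understates the change of low genes. Without a stated counting rule, reads of near-identical genes may be split between them.

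Gene lists were fixed before the data were examined, 54 in all, and 53 with at least 4 measured members were tested. Of 1335 entries, 1279 matched a name in the files. After the data were seen, 2 names were corrected: sdpC was matched to spbC, and the capsule gene pgsA to capA, since the files use pgsA for another gene. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Shares of TPM were compared with a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3.

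Genes were named by a rule fixed beforehand: the deleted genes and their neighbours, the 12 largest increases and 12 largest decreases among genes past the threshold with at least 10 TPM in the higher genotype and no overlap, up to 4 members with the largest changes per described list, and a fixed set of biofilm and stress genes. The planned comparison of dispersions assumed deposited counts and was not run on the recovered reads. The SD of log2 values between replicates took its place, and it also holds counting error. Chi-square per degree of freedom between replicates on recovered reads was 5.78 to 22.6, so no library looked like a copy of another.

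The test was tried on simulated data for this comparison, with 4231 genes in the step and a replicate CV of 0.08. Of 50 genes changed by each fold, 34% were recovered at 1.25-fold, 88% at 1.5-fold, and 100% at 2-fold and 4-fold, and 3.59% of calls were false. There 4031 of the 4231 genes were left unchanged, whereas 78.4% of genes passed in the data. The scaling and the rate of false calls were therefore not tried under so broad a change. None of the 53 lists passed camera there, where genes varied independently. A list whose members were all raised alike for this check did pass, which shows only that the test runs. The alternatives were other scalings and filters, ribosomal and transfer RNA rows kept, the replicate number as a block, limma-voom, leaving out each library, a test against a 1.5-fold change, an adjusted p of 0.01 and, chosen after seeing the data, other pseudocounts, genes of 300 bp or longer, sporulation genes and ssrA left out, and pairs of libraries for the replicate spread. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.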

Results

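Messenger RNA levels were measured in colony biofilms of Bacillus subtilis, a soil bacterium whose surface colonies hold matrix-producing, motile and sporulating cells side by side. Colonies of a wild-type strain and of a mutant lacking dnaK and tig were grown on LAGM agar for 24 h at 30 °C, with 3 biological replicates of each genotype. DnaK is an Hsp70 chaperone that helps proteins fold and refold, and tig encodes trigger factor, a chaperone bound to the ribosome that meets proteins as they are made. The series title places the comparison in a study of how impaired protein homeostasis affects the differences among cells of a biofilm. The deposited values were TPM, which are reads per gene length scaled to the same total in each library, for 4417 listed genes. Reads recovered from these values numbered 10811545, 11055249 and 12410088 in wild-type replicates 1, 2 and 3 and 16797667, 11291766 and 11798019 in mutant replicates 1, 2 and 3. Of these, 9319658 to 15575059 per library fell on genes other than ribosomal and transfer RNA.

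The deleted genes were examined first. In wild type, dnaK (positions 2626133 to 2627968, minus strand, in the files' own numbering) had 376 ± 20.3 deposited TPM (SD, n = 3) and tig (2886332 to 2887606, minus strand) had 729 ± 9.38 TPM (SD, n = 3). Both genes were listed at 0 in each of the 3 mutant libraries, so the labels and the data matched in all 6 libraries. Against a floor of 3 reads per mutant library, dnaK was at least 3519-fold lower and tig at least 4740-fold lower.

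Genes next to the deletions did not move as a block. Downstream of dnaK in the same operon, dnaJ, which encodes the Hsp40 partner of DnaK, rose by 2.23 ± 0.068 (log2 fold change ± SE, adjusted p = 6.1e-12, limma), and prmA and yqeU rose by 2.10 and 1.66. Upstream of dnaK, hrcA and grpE rose by 0.69 and 0.66, and hemN, which lies before hrcA, rose by 1.32. Beside tig, clpX differed by 0.05 (adjusted p = 0.53, limma) and fell by 0.17 under upper quartile scaling and by 0.24 without scaling, while ysoA rose by 0.56 and lonB by 2.26, and leuD was at -2.07, engB at -0.53, hemA at -0.43 and lonA at -0.29. Of 15 neighbours measured, 9 rose, 4 fell and 2 did not pass.

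Most of the transcriptome differed between the genotypes. Of 4238 genes tested, 3323 passed an adjusted p of 0.05 in limma, with 1649 higher and 1674 lower in the mutant. At least 2-fold, 863 genes were higher and 459 lower, a majority that turned over without scaling (691 higher and 768 lower) and was 731 against 671 under upper quartile scaling. The libraries of both genotypes did not overlap for 79.9% of the genes, where chance gives 10%. Without scaling beyond the TPM totals, 3495 genes passed and the split moved to 1289 higher and 2206 lower, 36.9% higher against 49.6%, and the median of all genes moved from -0.02 to -0.30. Under upper quartile scaling that median was -0.23, so small changes below are relative to the scaling used. Pearson correlations of log2 values were 0.993 to 0.995 within wild type, 0.996 within the mutant at both ends of the range, and 0.852 to 0.867 between genotypes. Ribosomal RNA-like rows took 15.02 ± 2.85% of reads in wild type and 7.80 ± 1.74% in the mutant (SD, n = 3 each, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows), a difference in library composition that ran along with every gene group described here.

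Sporulation genes were higher in the mutant throughout the developmental sequence. Of 143 measured genes in the 4 lists, 140 rose, none fell and the median log2 fold change was 2.11. The forespore list under sigma factor F rose in 18 of 18 members, the mother cell list under sigma E in 38 of 38, the later forespore list under sigma G in 37 of 39 and the late mother cell list under sigma K in 47 of 48. Adjusted over the list alone, 18, 38, 37 and 47 members rose. The spoIIQ gene, needed for engulfment, rose from 302 ± 27.9 to 2464 ± 72.9 TPM (SD, n = 3), and csfB rose by 3.05. The coat morphogenetic gene cotE rose from 491 ± 17.7 to 5151 ± 50.1 TPM, and safA rose by 2.96. The small acid-soluble spore protein gene sspC rose by 2.40, and the coat genes cotT and cotH rose by 3.31 and 2.74. The camera test with a preset correlation gave adjusted p = 1.75e-07, 5.34e-14, 7.41e-11 and 6.06e-15 for the lists of F, E, G and K, and each had adjusted p = 0.463 with an estimated correlation.

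Together the 4 sporulation lists took 6.71 ± 0.145% of TPM in wild type and 23.5 ± 0.616% in the mutant (SD, n = 3, exact permutation p = 0.1, two-sided). With the 10 most abundant genes left out, 5 of which were sporulation genes, the shares were 4.47 ± 0.102% and 15.72 ± 0.331% (SD, n = 3). The early sporulation list was less uniform, with 9 of 13 members higher, 2 lower and 2 not past the threshold (9 and 2 adjusted over the list alone). Its largest increases were in spoIIGA at 2.82 and sigE at 1.61. The master regulator gene spo0A differed by 0.11 (adjusted p = 0.15, limma) and fell by 0.17 without scaling. For this list the camera test gave adjusted p = 0.0125, and adjusted p = 0.622 with an estimated correlation.

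Genes for the biofilm matrix were also higher. All 15 members of the eps operon list, which encodes exopolysaccharide synthesis, rose at least 2-fold with a median of 1.81, led by epsB at 2.38 and epsA at 2.28. The amyloid fibre gene tasA rose from 548 ± 33.6 to 1730 ± 116 TPM (SD, n = 3), tapA rose by 1.87, sipW by 1.65, and yuaB, the surface hydrophobin gene also called bslA, by 1.58. Adjusted over the list alone, 15 of 15 and 4 of 4 rose. In camera the adjusted p = 3.17e-06 for eps and 0.0133 for the tapA list, and both had adjusted p = 0.463 with an estimated correlation. Of 25 measured biofilm regulator genes 9 rose, 9 fell and 7 did not pass (9 and 9 adjusted over the list alone), with camera adjusted p = 0.844, a median, mean and test that differed in sign, and a median that changed sign with scaling. The phosphatase gene rapB was at -3.01, abrB, which encodes a repressor of matrix genes, fell from 506 ± 35.8 to 168.2 ± 13.3 TPM (SD, n = 3), or -1.58, and kapD was at 1.59, while sinI was at 0.42, sinR at -0.31 and slrR at 0.76. The sinI change did not pass under upper quartile scaling or without scaling.

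**Figure D1:**
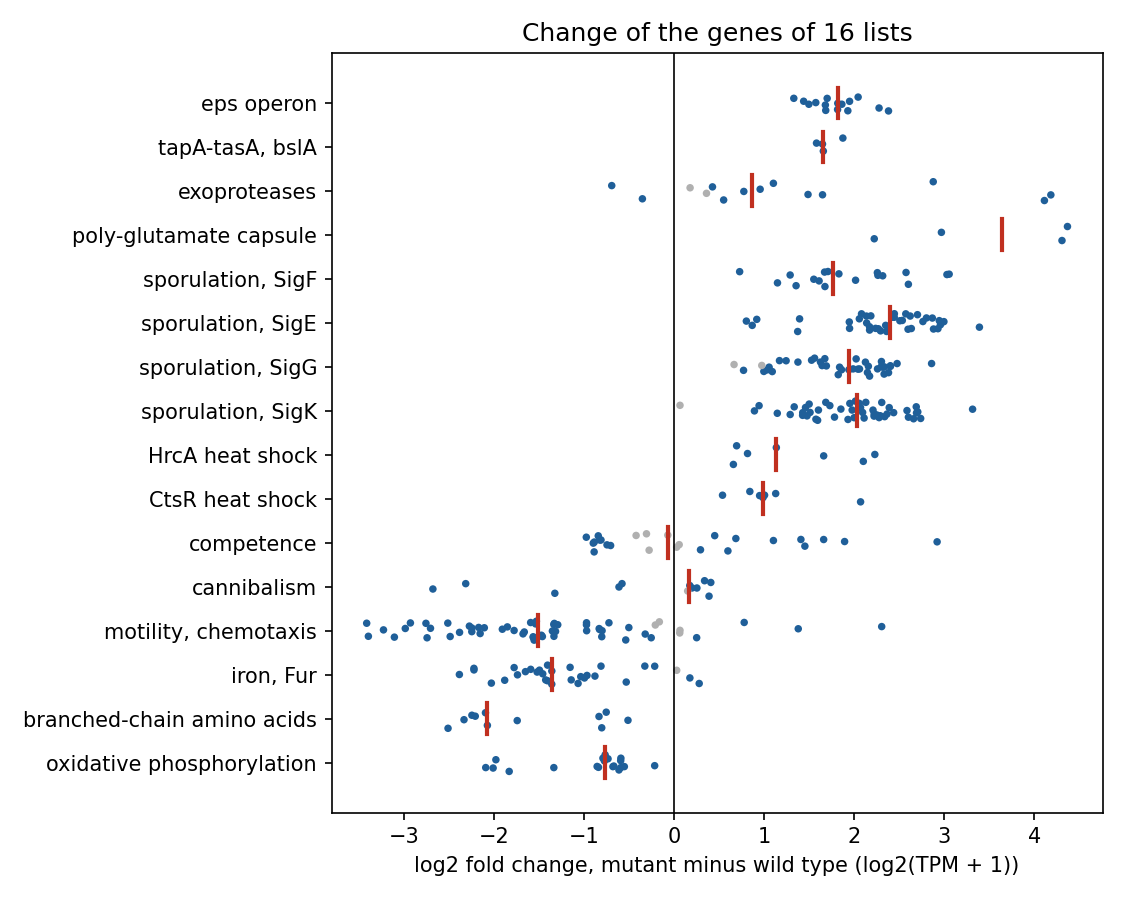
Log2 fold changes (horizontal axis, mutant minus wild type, on log2(TPM + 1)) of the members of 16 gene lists. The row of exoproteases also holds other degradative enzymes. Each point is a gene, blue where its adjusted p was below 0.05 and grey otherwise, and the red bar is the list's median; the eps, capsule, heat shock and 4 sporulation lists lie right of 0 and most motility genes lie left of it, at a median of -1.51.

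Secreted proteases and the poly-glutamate capsule showed some of the largest increases. The subtilisin gene aprE rose from 283 ± 28.4 to 5145 ± 301 TPM (SD, n = 3) and the neutral protease gene nprE from 113 ± 8.71 to 1963 ± 60.9 TPM, and mpr and wprA rose by 2.88 and 1.65. The list of exoproteases also holds other degradative enzymes, such as the amylase gene amyE. Of its 14 members 10 rose, 2 fell and 2 did not pass (10 and 2 adjusted over the list alone). The 2 that fell, bpr at -0.69 and epr at -0.35, are protease genes, named after their values were seen. The capsule genes capA, capE, capB and capC rose by 4.37, 4.31, 2.97 and 2.22, which is 4 of 4 (4 adjusted over the list alone). The response regulator gene degU rose by 1.45 and degQ, at 10.8 TPM in the mutant and 5 to 29 reads per library, by 1.56. The gene of its partner kinase, degS, named after its value was seen, went the other way, at -0.95. Camera gave adjusted p = 0.00595 for the exoprotease and degradative enzyme list and 0.00496 for the capsule. Both had adjusted p = 0.463 with an estimated correlation.

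Motility genes moved the other way. Of 58 measured motility and chemotaxis genes, 50 fell, 4 rose and 4 did not pass, with the same counts adjusted over the list alone and a median of -1.51. The flagellin gene hag dropped from 1406 ± 102 to 297 ± 39.9 TPM (SD, n = 3). The deepest falls in this list were flgC at -3.42, fliF at -3.40, fliE at -3.23 and fliG at -3.11, whereas sigD, which encodes the motility sigma factor, was at -0.83. The 4 that rose were swrA, an activator of swarming motility, at 2.30, yoaH at 1.38, hemAT at 0.78 and cheV at 0.25; these were named after their values were seen. Of the 6 members of the autolysin list, which also holds other genes such as pgdS, 4 fell and 2 rose (4 and 2 adjusted over the list alone). Those that fell were pgdS at -2.77, lytA at -2.46, lytB at -2.34 and lytC at -2.03. Of these, lytA, lytB and lytC lie side by side on the minus strand. The 2 that rose, named after their values were seen, were lytD at 0.91 and lytF at 0.27. Motility had adjusted p = 4.85e-11 in camera, with adjusted p = 0.463 with an estimated correlation, and the autolysin list had 0.141.

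Along the flagellar and chemotaxis operon, the fall was deepest near the start. Across its 31 genes from flgB to sigD, log2 fold change followed distance from flgB with Spearman's rho 0.941 and Pearson's r 0.902. Without the 2 end genes r was 0.896. The permutation p = 1e-05 for rho was the smallest possible, across genes, which are not independent replicates. The gradient was not part of the design and was examined after the data were seen, so this p is no independent test of it. The 10 genes nearest the start averaged 130.9 TPM in wild type and 15.5 TPM in the mutant, and the 11 at the end averaged 45.3 and 19.2 TPM. The last gene, sigD, was at 80.5 ± 5.81 TPM in wild type and 44.8 ± 3.78 TPM in the mutant (SD, n = 3). The flhF gene, chosen after its value was seen, stood apart from its neighbours. It was at 49.7 ± 0.288 TPM in wild type and 41.5 ± 1.498 TPM in the mutant (SD, n = 3).

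**Figure D2:**
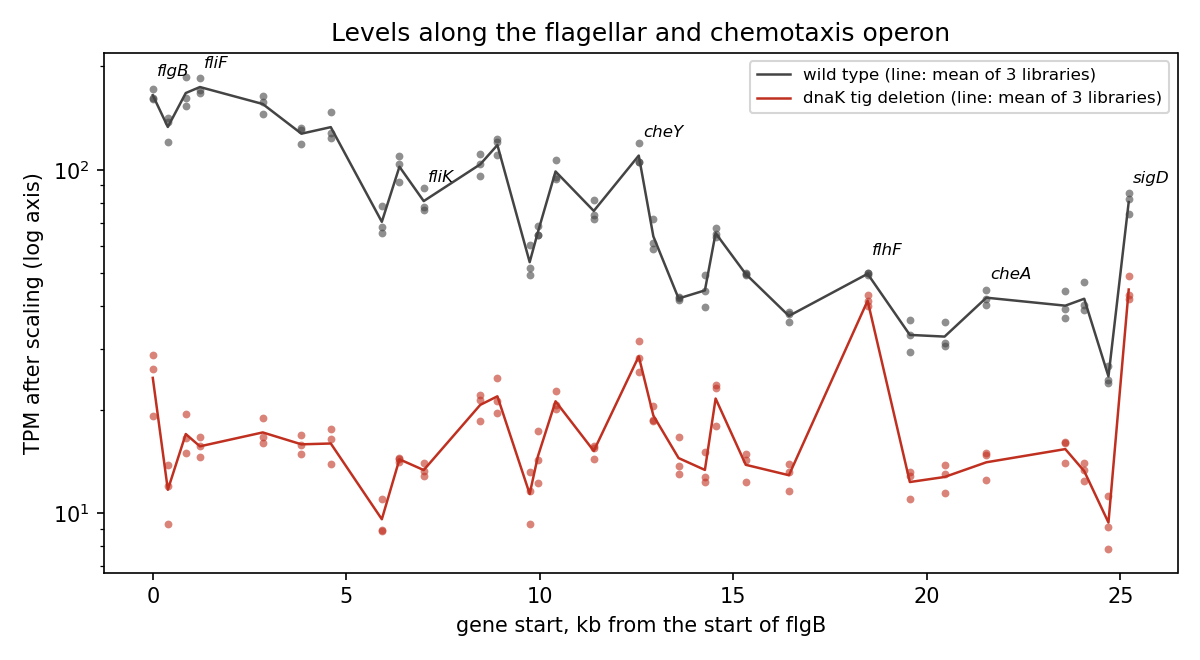
TPM after scaling (vertical log axis) of 31 genes by distance of the gene start from flgB in kb (horizontal axis), with a point for each library and a line through the mean of 3 libraries per genotype. Wild type declines along most of the operon and the mutant stays lower and flatter, with flhF at 49.7 and 41.5 TPM and sigD above its neighbours in both.

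Heat shock genes that answer to HrcA and CtsR were higher. All 7 measured HrcA genes rose, but 5 of them (hrcA, grpE, dnaJ, prmA and yqeU) lie in the dnaK operon beside the deletion, so that the count and test of this list rest mostly on that operon. The 2 that lie elsewhere were groES at 1.13 and groEL, the main chaperonin gene, from 1071 ± 72.4 to 1883 ± 101 TPM (SD, n = 3). All 7 CtsR genes rose as well, with clpE at 2.07, clpP at 1.13, mcsB at 1.00 and clpC at 0.95. Adjusted over the list alone, 7 and 7 rose. Other chaperone and protease genes did not follow, since of 20 measured 4 rose, 11 fell and 5 did not pass (4 and 11 adjusted over the list alone). Among them ypbH was at 1.33, htpG, the Hsp90 gene, was at -0.79, htrA at -0.76 and lonA at -0.29, while lonB, a protease gene of the forespore, was at 2.26. The HrcA list had adjusted p = 0.00279 and the CtsR list 0.00625 in camera, both with adjusted p = 0.463 with an estimated correlation, and the other chaperones had 0.191.

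Markers of other biofilm cell types went both ways. In the competence list 10 of 25 members rose and 9 fell (10 and 9 adjusted over the list alone). The largest changes were increases, in comER at 2.92, the regulator gene comK at 1.89, comGG at 1.66 and comGF at 1.45. Both comGG and comGF were low, at 5.32 and 5.16 TPM in wild type and 21 and 22 reads in their lowest library. Whether comER follows competence was not tested. The comGA gene was at 0.68, while the deepest fall was comFB, chosen after its value was seen, at -0.98. The median, the mean and the test of this list differed in sign. The cannibalism list had 6 of 12 members higher and 5 lower (6 and 5 adjusted over the list alone). The 5 that fell were sdp genes, with the immunity gene sdpI at -2.68 and sdpR at -2.32. The toxin gene spbC, also called sdpC, fell from 8526 ± 484 to 3402 ± 209 TPM (SD, n = 3). The 6 that rose were skf genes at 0.17 to 0.41, a split seen after the values were known. Rises of this size were near the shift of the all-gene median, which was -0.30 without scaling. The skfA gene was at 0.25 and lost its call under upper quartile scaling, without scaling, and when wild-type replicate 1 or 2 or mutant replicate 1 or 2 was left out (0.22, 0.16, 0.23 and 0.26 in that order). Camera gave adjusted p = 0.795 for competence and 0.559 for cannibalism, whose median, mean and test also differed in sign and whose median changed sign under upper quartile scaling and without scaling. The surfactin synthetase gene srfAA differed by 0.01 and was at -0.20 under upper quartile scaling and -0.27 without scaling.

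Most metabolic lists that passed in camera with the preset correlation were lower in the mutant, and only arginine synthesis was higher. Purine, pyrimidine, nitrogen, glycolysis, TCA cycle and carbon catabolite lists were also among the lower ones and are not detailed here. All 19 measured oxidative phosphorylation genes fell, with the quinol oxidase genes qoxC, qoxB, qoxD and qoxA at -2.09, -2.01, -1.98 and -1.83. All 11 branched-chain amino acid genes fell, 7 of them at least 2-fold, led by leuB at -2.51 and leuC at -2.33. These, with ilvB at -2.25 and ilvH at -2.21, lie in the stretch that ends at leuD, a neighbour of the tig deletion. An effect local to the deletion was therefore not told apart. However, the stretch and tig share the minus strand, so that tig lies downstream of the stretch. In addition, ysoA, between leuD and tig, rose by 0.56. In contrast, all 8 arginine genes rose, led by carA at 2.39 and argF at 2.33. Among 31 iron genes of the Fur regulon 28 fell, with the siderophore uptake gene feuA at -2.39, and in the acetoin list 9 of 13 fell, with alsD at -2.61 and alsS at -2.45. Outside metabolism, the PBSX prophage list rose in 28 of 32 members, with xkdM at 2.27. Adjusted over the list alone, the counts were 19, 11, 8, 28, 9 and 28. Camera gave adjusted p = 5.13e-06, 1.93e-05, 0.000476, 1.99e-08, 0.00279 and 3.02e-05 in that order, and with an estimated correlation adjusted p = 0.541 for oxidative phosphorylation and 0.463 for the other 5.

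The largest single changes lay partly outside these lists. The uncharacterised gene ywmD rose from 99.3 ± 7.69 to 2641 ± 125 TPM (SD, n = 3), and its neighbour ywmC rose by 3.71. The genes yjiA, yjfA, ymaF and ydaB rose by 3.86, 3.57, 3.68 and 3.55, the endoglucanase gene eglS by 3.66 and sacV by 3.98. The levanase gene sacC and its fructose uptake genes fell most, with levG at -5.15, levE at -5.15, levD at -5.02, levF at -4.74 and sacC at -4.44. They were followed by frlB at -4.21, yybF at -4.16, frlO at -3.88, the beta-glucoside transporter gene bglP at -3.67 and yhjG at -3.61.

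**Figure D3:**
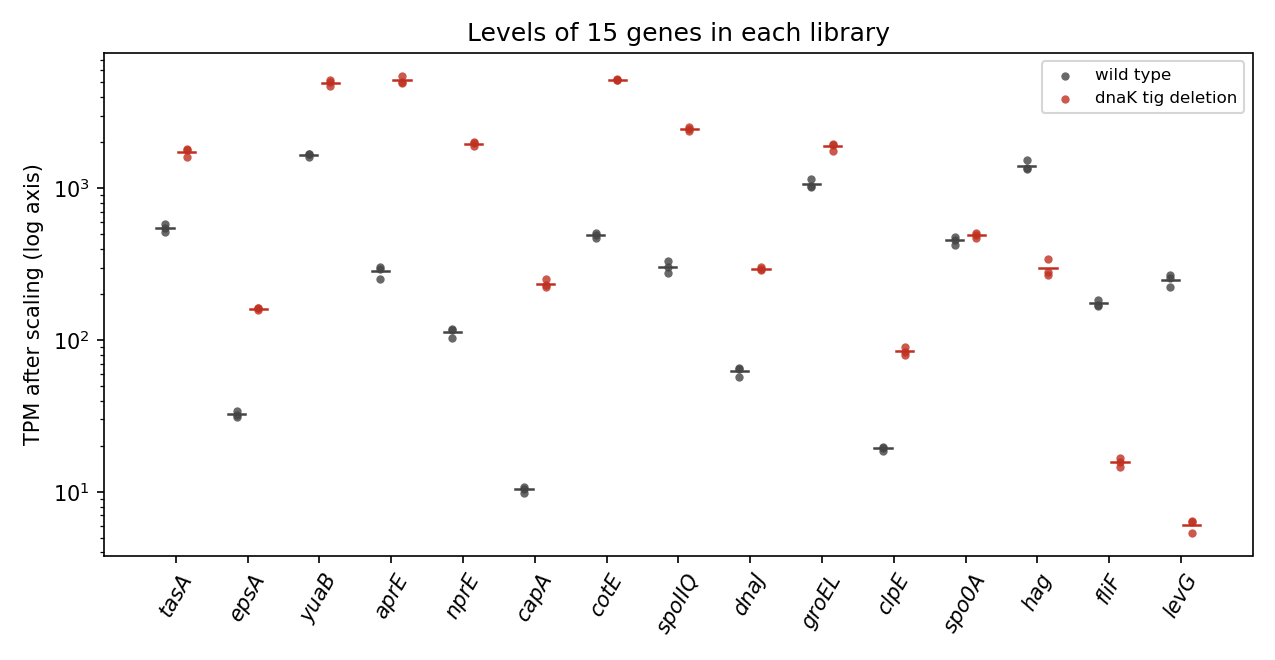
TPM after scaling (vertical log axis) of 15 genes in each of the 6 libraries, with a point per library and a bar at the mean of 3 libraries for wild type (grey) and the mutant (red). Matrix, protease, capsule, spore and heat shock genes are higher in all 3 mutant libraries, hag, fliF and levG are lower, and spo0A overlaps.

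Of 53 lists, 28 passed an adjusted p of 0.05 in camera, 13 higher and 15 lower. None passed with an estimated correlation, where the lowest adjusted p was 0.463 and 2 lists were at an unadjusted p under 0.05, and 45 passed in fry, which asks whether the genes of a list move, on balance, in a single direction and not whether they move more than other genes. The preset and the estimated correlation gave opposite outcomes, and neither was checked against real libraries without a genotype difference. In shares of TPM, 50 of 53 lists did not overlap between genotypes, 17 higher and 33 lower. These shares are of unscaled totals, in which the sporulation lists' larger share lowers that of others, so a lower share does not mean that a list's genes fell: the bacillaene list had 10 genes higher and 3 lower but a share ratio of 0.946. The median SD of log2 values between replicates was 0.108 in wild type and 0.0774 in the mutant, and 34.9% of genes spread more in the mutant. Much of the wild-type spread came with replicate 1: between pairs of libraries the median SD was 0.106 and 0.0884 with it and 0.074 without it, against 0.0575 to 0.0692 in the mutant. These are differences between replicate libraries of colony biofilms, which may also hold library preparation and depth, with no test.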

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

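Pseudocounts, the length minimum, pairs of libraries for the spread and leaving out sporulation genes with ssrA were chosen after seeing the data. The count of changed genes stayed between 3146 and 3495 over the planned scalings, filters, block and limma-voom, was 3155 to 3291 without single libraries, 2923 to 3327 under the alternatives chosen later, 2982 at an adjusted p of 0.01 and 1645 when tested against a 1.5-fold change, which asks for more than a difference. Of 1322 genes changed at least 2-fold, 1316 or more kept their call and direction without any single library. Genes at least 2-fold lower went from 459 to 768 without scaling and those higher from 863 to 691, so the majority turned over, where the median of all genes shifts down by construction. The planned count-based quasi-likelihood F test of edgeR was not run, since the values are TPM.

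Lists past the threshold were 22 to 29 over the alternatives of scaling, filter, block, pseudocount, gene length and libraries, but 0 with an estimated correlation and 45 in fry. With an estimated correlation the adjusted p was 0.463 for the HrcA, CtsR, eps, tapA and motility lists. It was the same for the exoprotease and degradative enzyme list and the 4 sporulation lists. Correlations were estimated on 4 residual degrees of freedom, and the cause was not tested.

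The direction of some small changes reversed with scaling: clpX was at -0.17 and -0.24 and srfAA at -0.20 and -0.27 under upper quartile scaling and without scaling, sigA was at -0.029 and -0.10, and spo0A at -0.17 and skfA at -0.032 without scaling. These follow the shift of the median. Of the differences in share, 89 values stayed within the spread between replicates and 15 moved beyond it, nearly all without the 10 most abundant genes, and none changed sign. In pairs of libraries, leaving out each wild-type library in turn, 35 to 45.7% of genes spread more in the mutant, the most without replicate 1. These are means over the mutant pairs, and single pairings ran from 32.6 to 47.3%. Over 243 named genes, 4291 of the alternative values kept direction and call, 24 lost the call and 3 gained it.

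With the replicate block, the changed genes numbered 3245. Same-numbered libraries did not deviate together (correlations -0.19, -0.15 and -0.14), and none correlated best with its own number, so the numbers were not taken as pairs. Depth did not limit most genes, but genes of a few reads have understated folds.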

Other observations

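Several gene groups that were not fixed lists changed together and were chosen after their values were seen. The ssrA gene below also counts among the 11 that fell in the list of other chaperone and protease genes. All 5 glycogen genes rose, from glgC at 2.45 to glgB at 3.15, with glgB going from 44.0 ± 1.16 to 398 ± 14.9 TPM (SD, n = 3). The 8 thiamine genes measured fell, with tenI at -3.08 and tenA at -3.06 but thiC at only -0.24. The genes cypX and yvmC, for pulcherriminic acid synthesis, were at -2.04 and -2.34, cypX from 10209 ± 988 to 2477 ± 196 TPM. The peptide gene yydF fell by 3.04, and yukE, a small secreted protein gene, fell from 3890 ± 172 to 1097 ± 97.8 TPM. Of 5 stable RNAs, 4 fell, with ssrS_2 at -1.36, ffs at -1.27, ssrA at -0.70 and ssrS_1 at -0.44, and rnpB, at -0.12, did not pass (adjusted p = 0.33, limma). The most abundant, ssrA, took 7.87 ± 1.81% of TPM in wild type and 4.03 ± 0.198% in the mutant (SD, n = 3, exact permutation p = 0.1, two-sided), with wild-type replicate 1 at 9.95%.

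The tests of scaling, gene length, operon position and pseudocount below were chosen after the results were seen. Sporulation genes were higher in the mutant, and 2 technical sources were weighed. The tables argued against scaling as the whole source, since the lowest median of the 4 lists over 4 scalings was 1.83. Shorter genes of other kinds were somewhat higher in the mutant, at a median of 0.505 up to 150 bp, but sporulation genes exceeded other genes of their length class by a median of 2.08. A difference in growth stage or in the sampling of the colonies could give the same result and stays open, since the labels name no batch and no other time point was analysed here. The genotype itself is the other open explanation.

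Genes downstream of dnaK rose more than those upstream. The mean of dnaJ, prmA and yqeU rose by 1.32 more than that of hrcA and grpE (SE 0.0581, exact permutation p = 0.1, two-sided, the smallest possible). Release of the heat shock repressor was not tested apart from this difference and stays open, since genes of a single operon need not move alike, as the flagellar operon below shows. Transcription entering from the deletion site may add to it: the smallest excess of the 3 genes over groES was 0.526, only just above the 0.5 set for this test. How the deletion was made is not given in the sources used here, and hemN, upstream, also rose by 1.32.

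The fall of the flagellar operon shrank with distance from its start. The floor of detection could give this if mutant reads were few, but the lowest read number of an operon gene in a mutant library was 34, for ylzI, close to the 30 set for the test. Shrinkage by the pseudocount would lose the gradient at a pseudocount of 0.1, where the end of the operon still exceeded its start by 1.70 in mean log2 fold change, taken over the 11 genes at its end and the 10 at its start. No biological explanation was tested.

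For chance, the 10 splits of the 6 libraries are too few for a share under 0.05. For changed genes 1 split, the real one, gave as many as 3323, and the highest other gave 0. For gene lists 1 split gave as many as 28, and the highest other gave 25. Each other split mixes the genotypes and so keeps part of their difference, which makes its count no level for an absence of change.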
